A study of Mus musculus with 6 samples.

How the data were processed

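RNA was profiled by droplet single-cell sequencing in HSCs sorted from mouse bone marrow, in 6 libraries of 1 mouse each: young and old, each fed freely, fasted for 24 hours, or fasted for 24 hours and refed for 24 hours. About 30000 cells were sorted and 10000 loaded per library, per the labels. Per the submitters' processing notes, the data were processed with Scanpy on the mm10 build. The aligner, the cell filters, the handling of doublets (droplets with more than 1 cell), the clustering settings and the statistical test are not given in the sources used here.

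The material was 22 tables that the authors deposited, a gene table and a pathway table for each of 11 clusters against all other cells of the pooled libraries. In the gene tables the authors give each gene's mean level as the log2 of counts scaled to 10000 per cell, and the fold change of the cluster against the rest in log2 units. The second value is unbounded below, so a gene with no count in a cluster takes a value near the constant added by the software. No fold is given for such genes, taken as those under -10; the deposited folds leave a gap there, between -14.0 and -5.80. The p-value deposited with each gene is a test over cells, with an adjusted p-value beside it. The method of adjustment was not checked here. In the pathway tables the authors' score is a signed test statistic over cells, beside a log2 fold change of the pathway score and a p-value with its adjustment. How cells were scored for a pathway is not given in the sources used here, and 12 pathways carry no fold. A pathway fold can match that of 1 gene: WikiPathways tamoxifen metabolism and Sult1a1 were both at -0.93 in cluster 0 in the authors' deposited tables. Members of pathways were not analysed here, so a named pathway is not a result apart from the genes. The deposited p-values treat cells as replicates, so they served as a filter on noise and are not reported as evidence of a difference between animals.

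Cell numbers per cluster were inferred from the deposited p-values. A gene detected in 1 cell gives a Welch statistic of 1 in size, whose p-value depends on the number of cells on that side alone. For 7 clusters the number was read from both sides of the comparison and for 4 from 1 side, and the 11 numbers added up to the total of 22378 cells read in the same way. The totals of the cells that held 1 of the 19 genes seen in a single cell had a median of 11707 counts (4239 to 22599). The equivalent depth of a cluster is the count per cell at which Poisson sampling of the mean profile over all cells leaves as many genes undetected as were undetected; its mean over cells was 12744. It assumes that every cluster shares that profile. A count of 0 was read as allowing up to 3 counts, and this limit covers counting error only.

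A gene was called higher or lower when its deposited log2 fold change was at least 0.5 in size and its deposited adjusted p under 0.05. The genes named for each cluster were the 10 highest and the 6 lowest among those called, in the order in which the authors listed them. Higher genes were read from the top and lower ones from the end, because no statistic stands in the gene tables. Names of the form Gm plus digits or ending in Rik were skipped. Up to 4 members with the largest change were added for each list that stood apart, and 4 autophagy and 4 glycolysis genes were read in every cluster. The text prints part of these. The 26 gene lists and 14 cell type marker lists were written before the data were examined, as were this size rule (fold and adjusted p together) and the comparisons of lists, clusters and pathways. Which tests in the closing observations came later is said there. List members absent from the tables under the names used, such as Dntt, Cd3e, Itgax and Prg2, were not analysed here.

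For each list and cluster the median deposited log2 fold change of the measured members (at least 3) was compared with the medians of 10000 random lists of the same size, drawn from genes matched in 20 bins of mean level. A list stood apart when it lay beyond the 0.5% of random lists at either end. Of 125 such calls 89 held when any 1 member was left out, and in 8 the mean and the median over members had opposite signs. The lists cover long-term HSC identity, quiescence, ageing, lymphoid, myeloid, megakaryocyte and erythroid priming, S phase, G2M phase, immediate early, heat shock, interferon, inflammation, antigen presentation, autophagy, lysosome, glycolysis, oxidative phosphorylation, mitochondrially encoded, fasting, stress response, cholesterol, MYC, nuclear RNA, sex-linked and ribosomal protein genes. The marker lists cover mature blood cells, endothelial cells, progenitors, cycling cells and long-term HSCs. All markers of long-term HSCs, lymphoid-primed progenitors, granulocyte-monocyte progenitors and cycling cells are also members of gene lists. So are most megakaryocyte and erythroid cell markers. A call on such a marker list and a call on its gene list are therefore not separate results. Relations between clusters were Pearson and Spearman correlations across the 17055 genes with a count, and again across the 8534 genes at or above the median mean level. The r that independent clusters of the same sizes would give was computed from their shares of cells. It assumes profiles of equal variance and no counting error, which clusters of unlike size and signature need not meet, so it is a rough guide. A limit of 0.4 for calling a relation and of 0.1 for calling it kept were set after the data were seen. Pathways were counted at a deposited adjusted p under 0.05 and named from the 5 strongest in each direction.

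The reading of cell numbers, the equivalent depth and the list comparison were tested on simulated data. Cell numbers were read exactly in 4 of 4 simulated clusters, and 5 simulated depths were recovered with a largest error of 1.92%. Of 200 simulated lists of 25 genes, 1.5% lay beyond the limits with no shift, 70.5% with a shift of 0.1 and 100% with a shift of 0.2 on the log2 scale. For this the folds of cluster 4 were shuffled between genes of like mean level, and members were drawn from genes at or above the median mean level. The rates do not cover lists whose members vary together, shorter lists or lists with rarely detected genes. Nor do they cover the small clusters, where many genes were undetected.

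Alternatives tried were other fold and p limits, leaving out genes below the median mean level, leaving out ribosomal, mitochondrially encoded and provisional names, unmatched random lists, the mean in place of the median, lists without shared members, and leaving out each member in turn. Gene coordinates are from GENCODE M21. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Comparisons of age and feeding were left out because they need values for each library, which were not analysed here.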

Results

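Haematopoietic stem cells (HSCs) were sorted from the bone marrow of Gfp-Lc3 mice, a strain that carries a fluorescent reporter of the autophagosome protein LC3, and profiled by droplet single-cell RNA sequencing. The 6 libraries came from young and old mice under 3 feeding conditions: fed freely, fasted for 24 hours, or fasted for 24 hours and refed for 24 hours. Each age and feeding group was 1 library from 1 mouse, so there was no replicate and no value below carries a between-animal error. The values used here were the authors' deposited tables of 11 clusters, numbered 0 to 10, each compared with all other cells pooled over the 6 libraries. Every table listed the same 17068 genes, of which 13 had no count in any cell. Clusters had been defined on these expression values, so a difference between a cluster and the rest is in part built in.

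The cluster sizes, read from the authors' deposited p-values, added up to 22378 cells. Clusters 0 to 4 held 4904, 3955, 3910, 3802 and 3747 cells, together 90.8% of the total. Cluster 5 held 1188 cells, and clusters 6 to 10 held 310, 267, 173, 112 and 10 cells, together 3.90%. Total counts per library were not analysed here. Counts per cell were estimated for each cluster from how many genes it left undetected; this equivalent depth lay between 9579 (cluster 7) and 15555 (cluster 4) in clusters 0 to 9 and was 49249 in cluster 10. A gene with no count in a cluster of this size allows a share of cells with a UMI (a counted molecule) of up to 0.968% in cluster 6, 1.12% in cluster 7, 1.73% in cluster 8, 2.68% in cluster 9 and 30% in cluster 10. It does not limit the share of cells that express the gene. The median log2 fold change over all genes was -0.32 in cluster 6, -0.17 in cluster 7 and 0.12 in cluster 10 in the authors' deposited tables, and it stayed within 0.1 of 0 elsewhere. Folds in those 3 clusters are to be read against that shift. Gene lists were compared with random lists of matched expression, which absorb it.

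**Figure D1:**
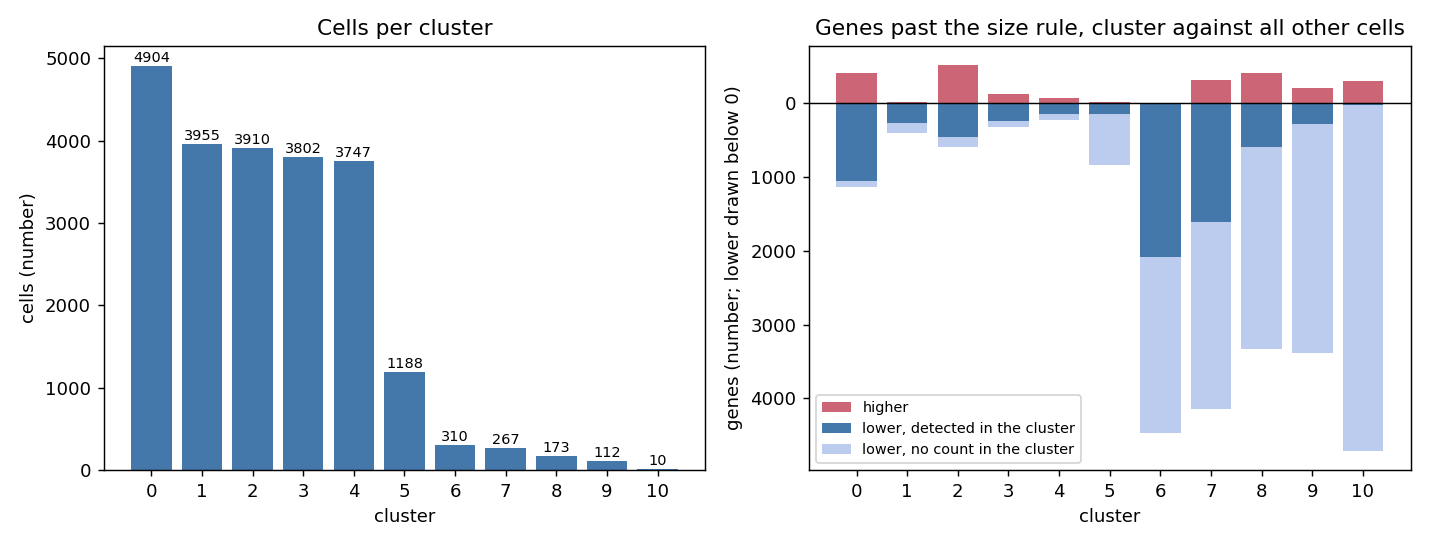
Cells in each cluster (left) and genes past the size rule against all other cells (right), in numbers, with genes lower in the cluster drawn below 0 and split by whether the cluster had any count. Clusters 0 to 4 hold 90.8% of cells, and most lower genes of clusters 8, 9 and 10 had no count in the cluster.

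The first question was which expression programs set the 11 clusters apart. Genes were called higher or lower when the authors' deposited log2 fold change was at least 0.5 in size and their adjusted p was under 0.05 (the size rule, which needs both). By this rule cluster 0 had 409 higher and 1130 lower genes, cluster 2 had 515 and 595, cluster 3 had 120 and 325, cluster 4 had 66 and 230, and cluster 1 had 21 and 410. In the smaller clusters the lower genes were mostly undetected ones, so 681 of the 832 lower genes of cluster 5, 2743 of 3333 in cluster 8, 3104 of 3390 in cluster 9 and 4684 of 4711 in cluster 10 had no count there. Of 40 gene and marker lists in 11 clusters, 125 of 440 pairs stood apart from matched random lists, 56 higher and 69 lower. If list members varied independently, like random genes, 4.4 would lie beyond the limits. Lists share members, members may vary together and clusters were defined on these values, so 4.4 is not the chance rate of these data. Without members held by another list, which leaves fewer lists, 46 pairs stood apart higher and 46 lower.

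**Figure D2:**
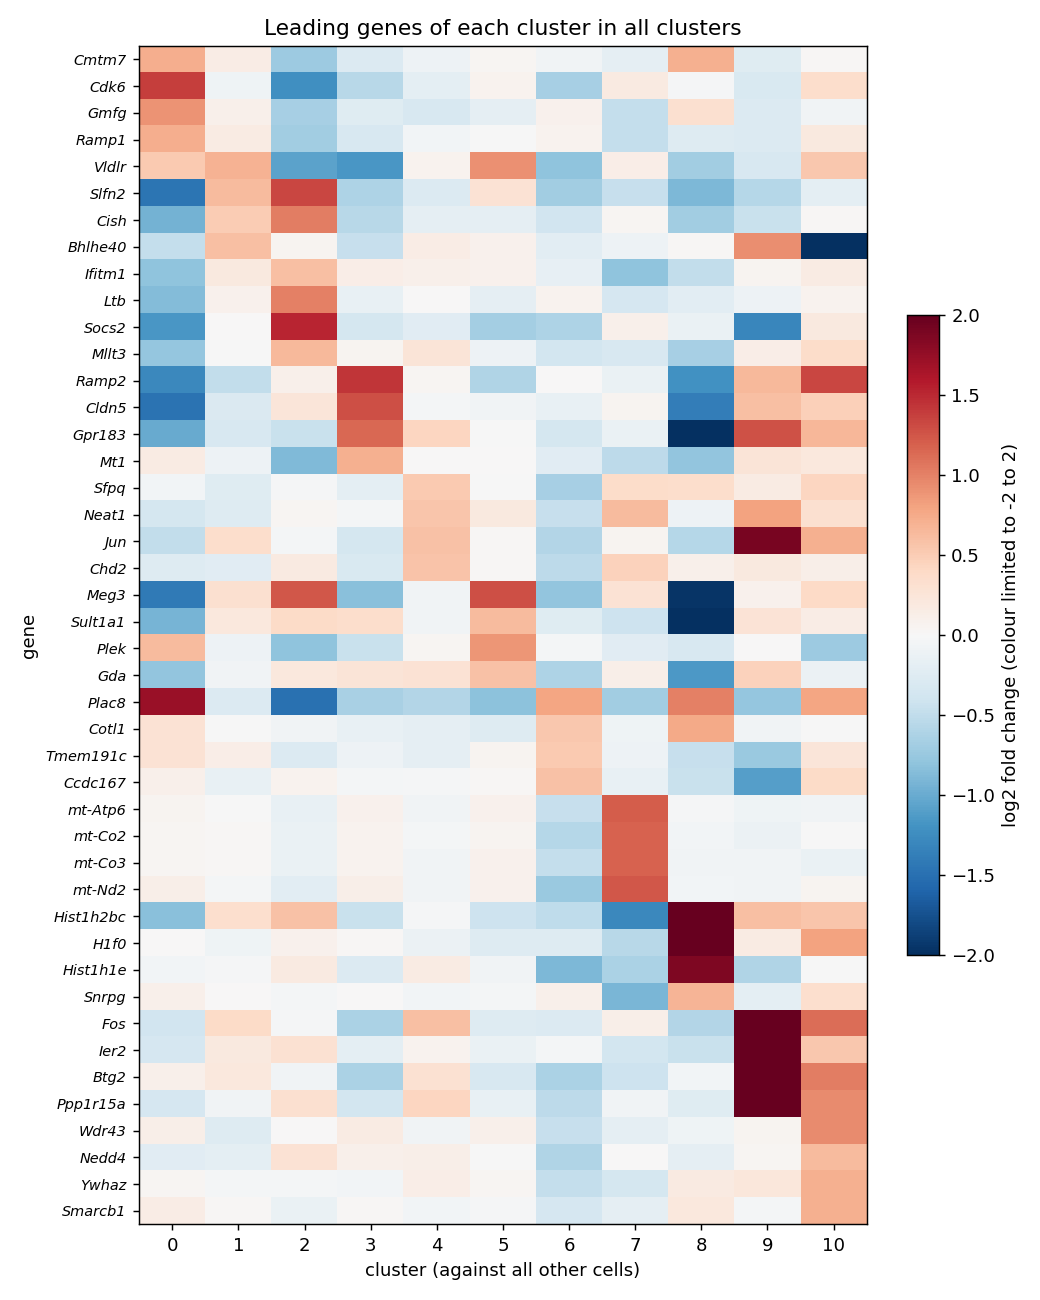
The log2 fold change (colour, limited to -2 to 2) of the leading genes of each cluster (vertical axis) in all 11 clusters (horizontal axis). Cdk6 and Slfn2 run in opposite directions in clusters 0 and 2, and Fos is highest in cluster 9.

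Cluster 0 had higher medians for megakaryocyte and lymphoid priming genes and lower medians for stem cell genes than matched lists. The lymphoid priming and lymphoid-primed medians turned to the low side without genes below the median expression, so they give no direction for well-detected genes. Myeloid priming (median 0.06, 3 higher and 2 lower of 18) and erythroid priming genes (0.02, 5 higher and 1 lower of 20) did not stand apart. Without genes below the median expression 4 lists stood apart on the high side of cluster 0, against 10 with all genes, and without members shared between lists 5 did. Cdk6, a cyclin-dependent kinase that governs exit from quiescence, was higher by 1.39 on the log2 scale in the authors' deposited table (chromosome 5, 3341485 to 3531008, mm10). The leading genes of that table also included Cmtm7 (0.73), Serpinb1a (1.39), Gmfg (0.90), Ramp1 (0.73), Crip1 (0.70), Runx3 (1.30) and the high-mobility-group gene Hmgb3 (0.77). Genes of the megakaryocyte lineage were higher: 6 of 9 megakaryocyte markers and 9 of 20 megakaryocyte priming genes passed, none in the other direction. The list medians were 0.79 and 0.41, and these lists share most of their members. The platelet glycoprotein genes Itga2b (1.17), Gp5 (1.31) and Gp1bb (1.56) led them in the authors' deposited table. Of 18 lymphoid priming genes 6 were higher, 2 were lower and 10 did not pass (median 0.59), with Cd48, a surface marker lost from the most primitive HSCs, at 1.71 and Tespa1 at 2.53 in the authors' deposited table. Mast cell or basophil markers were higher in 3 of 6 members (median 1.27), led by Fcer1a (3.39) and Cpa3 (1.62) in the authors' deposited table. The 9 lymphoid-primed progenitor markers had a median of 0.66 with 3 higher and 2 lower, and the 10 granulocyte-monocyte progenitor markers 0.52 with 2 higher, Ms4a3 at 1.69 in the authors' deposited table among them. Several of these genes were rarely detected. The log2 mean level was -7.60 for Cd48, -6.22 for Tespa1, -9.57 for Fcer1a, -5.70 for Cpa3, -6.64 for Gp1bb and -6.00 for Ms4a3. Their folds rest on few counts and do not describe most cells of cluster 0. Itga2b (-1.23) and Gp5 (-3.68) had higher mean levels.

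In the same cluster all 63 nuclear-encoded oxidative phosphorylation genes lay above 0 (median 0.13) and none passed the size rule. MYC and nucleolar genes (median 0.18, 1 of 26 higher), S phase genes (0.17, 0 of 27 past the rule) and cycling cell markers (0.23, 1 of 12 higher) also stood apart; Myc was at 0.52 and the topoisomerase gene Top2a at 0.54 in the authors' deposited table. Long-term HSC genes were lower. Of 21 identity genes 6 were lower and 15 did not pass (median -0.31). Of the 10 long-term HSC markers, all of them identity genes too, 4 were lower (median -0.44). The endothelial protein C receptor gene Procr (-0.94), the HSC maintenance regulator Mllt3 (-0.78), Ly6a (-0.79), Fgd5 (-0.69), Mecom (-0.55) and Ifitm1 (-0.80) were among them in the authors' deposited table. The cell cycle inhibitor gene Cdkn1c (-0.91) and Ndn (-0.55) fell among 3 of 17 quiescence genes (median -0.15) in the authors' deposited table. Ageing genes were lower in 9 of 31 members (median -0.19), including Sult1a1 (-0.93), Gpr183 (-1.01) and Neo1 (-0.82) in the authors' deposited table. Slfn2 (-1.45), the lymphotoxin gene Ltb (-0.87) and the imprinted transcript Meg3 (-1.41) were further lower genes of the authors' deposited table. Further shifts below 0 were found for immediate early genes (median -0.32, 4 of 26 lower), interferon response genes (-0.19, 1 lower and 1 higher of 29), inflammation genes (-0.15, 4 lower and 1 higher of 27), stress response genes (-0.07, 3 lower and 2 higher of 26), nuclear RNA (-0.41, 3 of 7 lower) and endothelial markers (-0.45, 1 of 12 lower).

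The authors' deposited pathway table scored 1531 pathways higher and 764 lower in cluster 0, with the BioCarta G1 set (log2 fold change 0.25) and the Reactome pentose phosphate set (0.25) among the highest. When genes below the median expression were left out, the lymphoid priming and lymphoid-primed medians of cluster 0 turned to the low side, at the 1.02nd and 0.26th percentile of matched lists. Leaving out 1 member ended the mast cell or basophil, stress response, nuclear RNA and endothelial calls of this cluster. The lower members of the nuclear RNA list were Snhg11 (-1.84) and the imprinted neighbours Meg3 (-1.41) and Mirg (-0.99) in the authors' deposited table.

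Many of the genes that set cluster 0 apart ran the other way in cluster 2, although ageing genes had medians below matched lists in both. Slfn2 (1.33), Ltb (1.01), Meg3 (1.24), Cdkn1c (0.92) and Mllt3 (0.65) were higher in the authors' deposited table, where the cytokine feedback inhibitors Socs2 (1.53) and Cish (1.03), Lst1 (0.88) and Pik3r1 (0.68) also led. Mllt3 lies on chromosome 4 at 87769925 to 88033364 and Ifitm1 (0.60 in the authors' deposited table) on chromosome 7 at 140967221 to 140969825 (mm10). Of 21 long-term HSC identity genes 5 were higher and 16 did not pass (median 0.24). Of the 10 long-term HSC markers, all of them identity genes too, 3 were higher (median 0.45). Ctnnal1 was at 0.71, Ly6a at 0.55 and Fgd5 at 0.52 in the authors' deposited table. Quiescence genes were higher in 2 of 17 members (median 0.18), among them Klf6 (0.62) in the authors' deposited table. Interferon response genes had a median of 0.30, with 26 of 29 above 0, 4 higher and 1 lower. The interferon-induced genes Ifit3 (1.48), Ifit1 (0.66), Iigp1 (0.64) and Ifi44 (0.52) were the 4 higher ones in the authors' deposited table.

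Genes lower in cluster 2 included Cdk6 (-1.22), Serpinb1a (-1.52), Runx3 (-1.45), Cmtm7 (-0.73), Crip1 (-0.88) and Ramp1 (-0.70) in the authors' deposited table. Lymphoid priming genes were lower in 6 and higher in 1 of 18 (median -0.68), megakaryocyte priming genes lower in 5 of 20 (median -0.25), and erythroid priming genes lower in 5 of 20 (median -0.25). Gp5 (-1.26), Itga2b (-1.07) and Plek (-0.80) were lower in the authors' deposited table. Lineage marker lists also had medians below matched lists: mast cell or basophil (median -1.27, 2 of 6 lower), lymphoid-primed (-0.75, 3 lower and 1 higher of 9), granulocyte-monocyte progenitor (-0.45, 2 of 10 lower), megakaryocyte (-0.41, 2 of 9 lower) and erythroid cell (-0.41, 2 of 11 lower). Apart from the mast cell or basophil list, these share most or all members with priming lists and are not separate support. Ageing genes were lower in 7 of 31 (median -0.15), among them the metallothionein genes Mt1 (-0.88) and Mt2 (-1.05), Gstm2 (-0.83) and Aldh1a1 (-0.76) in the authors' deposited table. Mitochondrially encoded (-0.13), MYC and nucleolar (-0.13) and oxidative phosphorylation genes (-0.08) had medians below 0, with no member past the rule. Immediate early (0.16, 1 of 26 higher), cholesterol synthesis (0.14, 0 of 22) and stress response genes (0.10, 2 higher and 1 lower of 26) had medians above 0. The authors' deposited pathway table listed 1380 higher and 724 lower pathways, with KEGG JAK-STAT signalling at 0.12 and a Reactome set of non-canonical NF-kB receptors at 0.36. Without genes below the median expression, the lymphoid priming and lymphoid-primed lists of cluster 2 turned to the 76.5th and 66.5th percentile. The erythroid priming, mitochondrially encoded, stress response, mast cell or basophil, erythroid cell and granulocyte-monocyte progenitor calls ended without 1 member.

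Across genes at or above the median expression (8534 genes), the fold changes of clusters 0 and 2 had a Pearson r of -0.81, against an r of -0.29 that 2 independent clusters of their sizes would give because each is part of the other's rest. On all genes r was 0.03, where genes undetected in either cluster enter with very large negative folds.

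Cluster 3 was marked by genes of HSC ageing. All 31 measured ageing genes lay above 0 (median 0.34) and 6 passed: Gpr183 (1.14), the metallothionein genes Mt2 (0.93) and Mt1 (0.71), the von Willebrand factor gene Vwf (0.60) and the clusterin gene Clu (0.51) were among them in the authors' deposited table. The receptor activity-modifying protein gene Ramp2 (1.43; chromosome 11, 101246028 to 101259546, mm10) and the tight junction gene Cldn5 (1.28) led the authors' deposited table, with Sbspon (0.86), Rbm19 (0.57) and the spermidine synthase gene Srm (0.51). MYC and nucleolar genes had a median of 0.19 with 24 of 26 above 0 and 1 past the rule. Immediate early genes were lower in 6 of 26 members (median -0.35), with Egr2 at -1.52, Egr3 at -0.75, Nr4a1 at -0.70 and Fos at -0.63 in the authors' deposited table. The very-low-density lipoprotein receptor gene Vldlr (-1.16; chromosome 19, 27216484 to 27254231), Serpinb1a (-0.74), Cdk6 (-0.55), Vim (-0.52) and Ctla2a (-0.51) were lower in the authors' deposited table.

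Lists of differentiating cells stood apart on the low side in cluster 3: erythroid cell (median -1.52, 4 of 11 lower), mast cell or basophil (-1.12, 3 of 6), lymphoid-primed (-0.71, 1 of 9), lymphoid priming (-0.52, 4 of 18), erythroid priming (-0.38, 5 of 20), myeloid priming (-0.18, 3 of 18) and megakaryocyte (-0.17, 1 of 9). Cycling cell (-0.16), interferon response (-0.12), G2M phase (-0.12), inflammation (-0.10) and cholesterol synthesis (-0.09) medians were also below matched lists, with at most 2 members past the rule in each. The authors' deposited pathway table scored 781 pathways higher and 844 lower, with Reactome tight junction interactions at 0.35 and the WikiPathways blood clotting cascade at 0.47 among the highest and Reactome VLDL clearance at -0.59 among the lowest. Of the 13 low-side lists of cluster 3, 8 held without any 1 member. The myeloid priming, G2M phase, mast cell or basophil, megakaryocyte and cycling cell calls did not. By the mean over members 7 lists stood apart there, and 7 did without members held by another list.

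Cluster 4 expressed immediate early genes at moderately higher levels. Jun (0.59), Fos (0.61), Fosb (0.66) and Egr3 (0.57), transcription factor genes induced within minutes of stimulation, were the 4 of 26 immediate early genes that passed (median 0.26) in the authors' deposited table. The splicing factor gene Sfpq (0.52; chromosome 4, 127021324 to 127037013, mm10), the nuclear long non-coding RNA Neat1 (0.55), the chromatin remodeller gene Chd2 (0.57), the HSC transcription factor gene Erg (0.51), mt-Nd6 (0.55) and Cep350 (0.54) also led the authors' deposited table. Quiescence genes (median 0.18, 13 of 17 above 0), ageing genes (0.14, 26 of 31), long-term HSC markers (0.13, 10 of 10) and identity genes (0.10, 18 of 21) stood apart although no member passed. The 10 long-term HSC markers are all identity genes too. Without members held by another list, 3 lists stood apart on the high side of cluster 4, against 5 with them. Hlf was at 0.35 and Mecom at 0.29 in the authors' deposited table, neither past the rule. Plac8 (-0.58), Gp5 (-0.69), the growth factor genes Fgf3 (-0.94) and Pdgfc (-1.46), and Angptl4 (-0.73) were lower in the authors' deposited table. Oxidative phosphorylation genes had a median of -0.09, with 1 of 63 above 0 and 0 past the rule, and MYC and nucleolar genes a median of -0.09. Megakaryocyte markers (-0.37, 1 of 9 lower) and lymphoid-primed markers (-0.18, 1 of 9 lower) had medians below 0. The KEGG oxidative phosphorylation set was at -0.06 in the authors' deposited pathway table, which held 1191 higher and 692 lower pathways. The lymphoid-primed call turned to the 74.1st percentile without genes below the median expression, and it and the long-term HSC marker call ended without 1 member.

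Among clusters 0 to 4, cluster 1 had the fewest higher genes. The 21 higher genes included Vldlr (0.70), Slfn2 (0.64), Cish (0.51), the circadian repressor gene Bhlhe40 (0.59), the small heat shock gene Hspb1 (0.63), Wfdc17 (0.61) and the cystine transporter gene Slc7a11 (0.73) in the authors' deposited table. Immediate early (median 0.11), antigen presentation (0.08), ribosomal protein (0.06) and interferon response genes (0.05) stood apart with no member past the rule. The class II antigen presentation genes Cd74 and H2-Eb1 were at 0.43 and 0.45 in the authors' deposited table. The erythroid transcription factor gene Gata1 (-1.67) and the erythropoietin receptor gene Epor (-0.76) were lower in the authors' deposited table, among 5 of 20 erythroid priming genes (median -0.19). MYC and nucleolar genes were below matched lists (median -0.20, 1 of 26 lower), with Rrp12, a ribosome assembly gene, at -0.55 and the amino acid transporter gene Slc7a5 at -0.70 in the authors' deposited table. T or NK cell (-0.48, 1 of 7 lower), megakaryocyte (-0.24, 1 of 9), cycling cell (-0.23, 0 of 12) and cholesterol synthesis medians (-0.14, 0 of 22) were also below. The authors' deposited pathway table scored 269 pathways higher and 1834 lower, with Reactome translation elongation at 0.05 and WikiPathways mRNA processing at -0.09. Reactome cellular response to starvation was at 0.03, beside WikiPathways cytoplasmic ribosomal proteins at 0.04, in the authors' deposited table. Genes shared between these sets were not analysed here, so the starvation set is not read as a response to fasting. The mean over ribosomal protein genes lay at the 28.0th percentile, so that call holds for the median and not for the mean. On the low side MYC and nucleolar genes were the 1 list of 6 that held without any 1 member, and 2 lists stood apart there by their mean.

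Cluster 5 had 23 higher genes, and 151 of its 832 lower genes were detected in it. The imprinted neighbours Meg3 (1.28; chromosome 12, 109541001 to 109571726), Rian (1.17) and Dlk1 (1.25), the transcription cofactor gene Eya4 (1.99), Vldlr (0.91), Plek (0.88), Wfdc17 (1.18), the metalloprotease inhibitor gene Timp3 (0.82), Sult1a1 (0.63) and Gda (0.58) were higher in the authors' deposited table. Of 31 ageing genes 2 were higher and 21 lay above 0 (median 0.13), and of 7 nuclear RNAs 1 was higher (median 0.19). Medians between 0.04 and 0.08 stood apart for megakaryocyte priming (1 of 20 higher) and, with no member past the rule, mitochondrially encoded, antigen presentation, glycolysis and MYC and nucleolar genes. On the low side stood erythroid cell (-0.62, 1 of 11 lower), lymphoid-primed (-0.39, 0 lower and 1 higher of 9), erythroid priming (-0.26, 2 of 20 lower), megakaryocyte (-0.24), cycling cell (-0.22), immediate early (-0.14, 2 of 26 lower) and oxidative phosphorylation genes (-0.04). Kcp, Syt9 and Nlgn3 had no count in the cluster, and Mycn was at -0.60 in the authors' deposited table. That cluster's pathway table, from the authors' deposited tables, listed 177 higher and 335 lower pathways, with Reactome VLDL clearance at 0.63 and WikiPathways vitamin A and carotenoid metabolism at 0.23. The lymphoid-primed list moved to the 98.6th percentile without genes below the median expression. Of 7 lists on each side of cluster 5, 4 higher and 3 lower ones held without any 1 member, and 3 higher and 1 lower list stood apart by the mean; with undetected genes at 3 counts, 4 lower ones did.

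Cluster 6 had 8 higher genes against 4466 lower ones, 2383 of them undetected. Plac8 (0.79; chromosome 5, 100553725 to 100572245), the actin-binding gene Cotl1 (0.54), the cathepsin gene Ctss (0.98), the galectin gene Lgals1 (0.55), Tnfaip8l2 (1.04), Ccdc167 (0.59), Tmem191c (0.53) and the beta-globin gene Hbb-bs (1.99) were the 8 in the authors' deposited table. Mitochondrially encoded genes were lower in 11 of 13 members (median -0.74), with mt-Nd4l at -1.18, mt-Nd5 at -1.04 and mt-Nd1 at -0.97 in the authors' deposited table. Quiescence genes were lower in 7 of 17 members (median -0.49), including Nr4a1 (-1.07), and nuclear RNA in 4 of 7 (median -0.79), including Kcnq1ot1 (-1.07), in the authors' deposited table. Markers of mature blood cells stood apart on the high side: erythroid cell (median 3.26), T or NK cell (2.31) and monocyte or macrophage (0.53). Few members passed: 1 higher and 1 lower of 11 erythroid cell markers, 0 of 7 T or NK cell markers, and 0 higher and 2 lower of 12 monocyte or macrophage markers. The haem synthesis gene Alas2 was at 5.79, the T cell receptor gene Trbc2 at 5.46 and the chemokine receptor gene Ccr2 at 5.22 in the authors' deposited table, none past the rule. Erythroid priming (0.66, 1 higher and 1 lower of 20), cycling cell (0.12), oxidative phosphorylation (0.08), lymphoid priming (0.07, 2 of 18 lower) and ribosomal protein (0.04) medians also stood apart on the high side. F8, Prx and Lox had no count in the 310 cells. The authors' deposited table of pathways scored 8 higher and 2449 lower, with WikiPathways cell cycle at -0.28. Without 1 member the monocyte or macrophage, lymphoid priming, cycling cell and nuclear RNA calls of cluster 6 ended.

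Cluster 7, with 314 higher and 4148 lower genes, was set apart by its mitochondrial transcripts. All 13 mitochondrially encoded genes were higher (median 1.17), among them mt-Atp6 (1.21; mitochondrial genome, 7927 to 8607), mt-Co2 (1.17), mt-Co3 (1.18), mt-Nd2 (1.25) and mt-Nd4l (1.30) in the authors' deposited table. Nuclear RNAs were higher in 3 of 7 members (median 0.63), with Kcnq1ot1 at 0.90, Malat1 at 0.63 and Neat1 at 0.63 in the authors' deposited table. Ribosomal protein genes were lower in 79 of 83 members (median -0.91) and nuclear-encoded oxidative phosphorylation genes in 50 of 63 (median -0.64). Rps13 (-1.14), Rpl27 (-1.13), Rps15a (-1.13), Uqcrh (-1.01), Atp5e (-0.93) and Cox7b (-0.92) were examples in the authors' deposited table. Interferon response genes were lower in 10 of 29 members (median -0.45), led by Ifit3 (-1.98), Zbp1 (-1.12) and Gbp2 (-1.04) in the authors' deposited table. Of 5 sex-linked genes 1 was higher (median 0.53), the Y-linked Eif2s3y at 0.54 in the authors' deposited table. Begain, S100a5 and Dach2 had no count in the 267 cells. The Reactome set for ATP formation by chemiosmotic coupling was at 0.62 and its set for proteasomal degradation of GLI1 at -0.46 in the authors' deposited pathway table, with 187 pathways higher and 1506 lower. Which members gave the ATP formation set its value was not analysed here, so it may repeat the mitochondrially encoded genes. Leaving out 1 member took the nuclear RNA list to the 98.8th percentile and so ended its call, and the sex-linked call ended in the same way.

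Cluster 8 had 404 higher genes, with histone genes at their head, and low levels of HSC ageing genes. The histone genes Hist1h2bc (4.06; chromosome 13, 23684199 to 23692908), Hist1h1c (2.71), H1f0 (2.47; chromosome 15, 79028450 to 79030504) and Hist1h1e (1.87) led the authors' deposited table, with Ptms (1.57), Vim (1.17), Rbm3 (0.83), Cmtm7 (0.71), the spliceosome gene Snrpg (0.68) and the thioredoxin gene Txn1 (0.68). Oxidative phosphorylation genes lay above 0 in 61 of 63 members (median 0.34), and Ndufa1 (0.59), Uqcrc1 (0.56) and Atp5b (0.51) passed in the authors' deposited table. Ageing genes were lower in 22 of 31 members (median -0.82), among them Gpr183 (-2.26), Sult1a1 (-2.03), Neo1 (-1.61) and Cd38 (-1.26) in the authors' deposited table. The class II genes H2-Aa (-1.81), H2-Eb1 (-1.61) and Cd74 (-1.57) were lower among 4 of 20 antigen presentation genes (median -0.11) in the authors' deposited table. Of 21 long-term HSC identity genes 4 were lower and 1 higher (median -0.13), with Ly6a at -1.16 and Procr at -0.80 in the authors' deposited table. Nuclear RNA (-1.33, 4 of 7 lower, with Meg3 at -1.96 in the authors' deposited table), cholesterol synthesis (-0.21, 5 of 22), immediate early (-0.19, 6 of 26) and ribosomal protein medians (-0.06, 0 of 83) were below matched lists. Mapk13, Zcwpw1 and Kcnb2 had no count in the 173 cells. Reactome transcription termination by RNA polymerase II (0.30) was among 1608 higher pathways of the authors' deposited table, against 186 lower ones.

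Cluster 9 had 205 higher genes and carried a strong immediate early program. Of 26 immediate early genes 24 were higher, 2 did not pass and none was lower (median 2.47). Fos (3.26; chromosome 12, 85473890 to 85477273), Egr1 (2.35), Junb (2.25), Ier2 (2.38), Zfp36 (3.04), Klf2 (3.90), Nr4a1 (4.56) and Atf3 (5.89) were among them in the authors' deposited table. Quiescence genes were higher in 7 of 17 members (median 0.45), including the cell cycle inhibitor gene Cdkn1a (3.34), the Notch target Hes1 (4.29) and Btg2 (3.18) in the authors' deposited table. Without members held by another list, the quiescence median was 0.28. Inflammation genes were higher in 6 and lower in 2 of 27 (median 0.45), with Nfkbiz at 2.72 in the authors' deposited table. Ageing genes were higher in 5 of 31 members (median 0.39), with Gpr183 at 1.27 in the authors' deposited table. Fasting, FOXO and glucocorticoid genes had a median of 0.19, with 3 higher, 3 lower and 25 not past the rule. The glucocorticoid-induced kinase gene Sgk1 (2.00), the insulin receptor substrate gene Irs2 (1.15) and Klf9 (0.86) were the 3 higher ones in the authors' deposited table. Oxidative phosphorylation genes had a median of -0.10 with 1 of 63 lower. Erythroid priming genes had 8 of 20 undetected. Their median with undetected genes set at 3 counts lay at the 42.1st percentile, and at the 99.7th without genes below the median expression, so no direction is given. Means over the inflammation and fasting lists had the opposite sign to their medians (-0.74 and -1.09). The authors' deposited pathway table listed 774 higher and 78 lower pathways, including the PID AP1 set (0.69).

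Cluster 10 held 10 cells, and 4910 genes had no count there. Wdr43, a ribosome biogenesis gene (0.94; chromosome 17, 71615895 to 71659031), Tox4 (1.09), Ppp6r1 (1.01), Usp19 (0.94), Ywhaz (0.71), Smarcb1 (0.71) and Nedd4 (0.63) were among its 305 higher genes in the authors' deposited table. S phase genes had a median of 1.12, with 25 of 27 above 0, 3 higher and 1 lower, and MYC and nucleolar genes a median of 0.53, with 26 of 26 above 0 and 3 higher. Immediate early genes had a median of 0.70 with 1 higher and 3 lower of 26, and their mean lay at the 49.2nd percentile. Ribosomal protein genes had a median of -0.02 (1 of 83 lower). Pathways were higher in 1875 cases and lower in 27 in the authors' deposited table, with Reactome carbohydrate metabolism at 0.25.

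**Figure D3:**
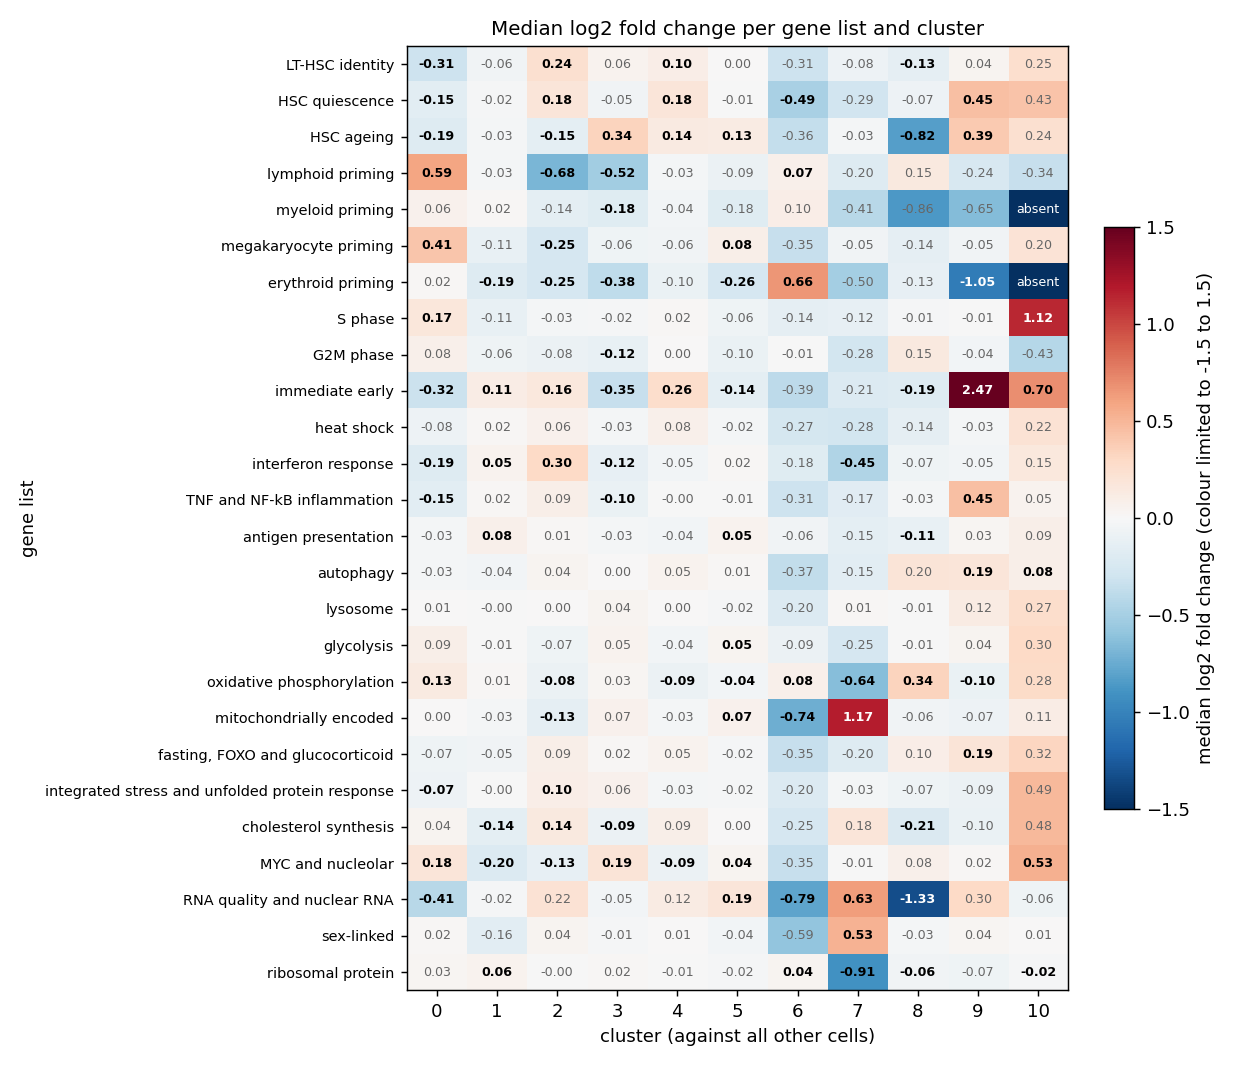
Median log2 fold change (colour, limited to -1.5 to 1.5) of 26 gene lists (vertical axis) in 11 clusters against all other cells (horizontal axis), with bold figures where a list stands apart from matched random lists and "absent" where most members had no count. Immediate early genes reach 2.47 in cluster 9 and ribosomal protein genes fall to -0.91 in cluster 7.

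**Figure D4:**
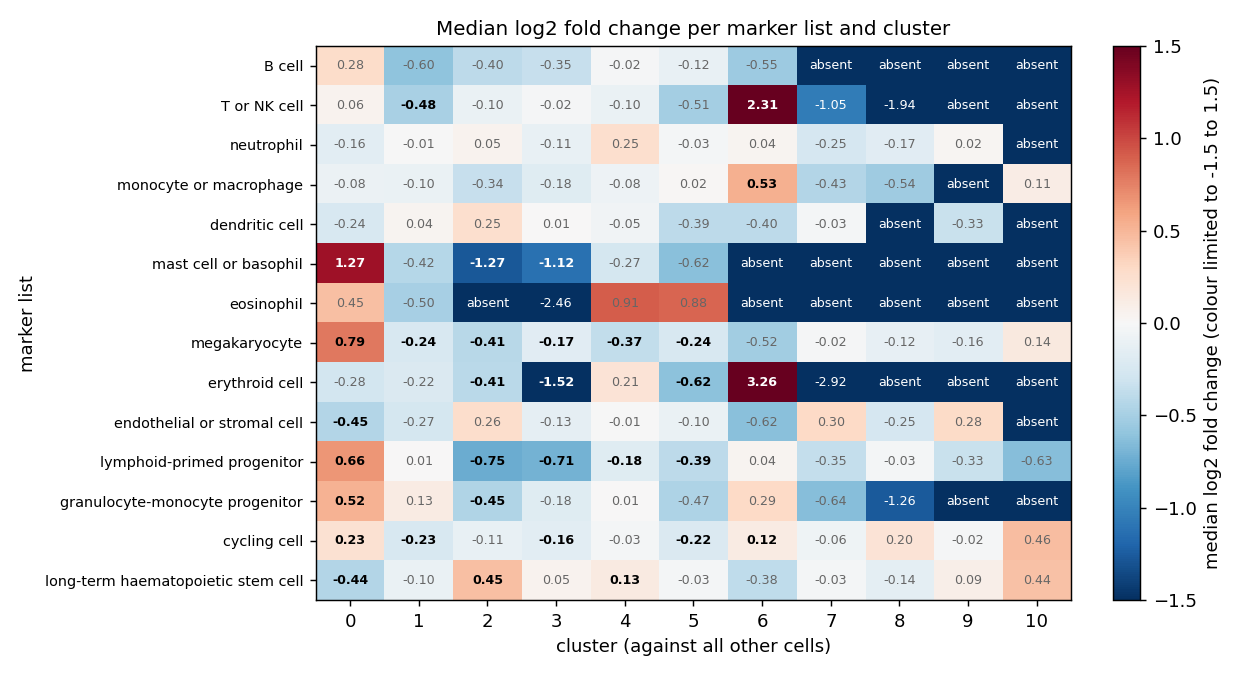
Median log2 fold change (colour, limited to -1.5 to 1.5) of 14 cell type marker lists (vertical axis) in 11 clusters (horizontal axis), drawn in the same way. Erythroid cell markers reach 3.26 in cluster 6, and long-term HSC markers are at -0.44 in cluster 0 and 0.45 in cluster 2.

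The series asks about autophagy in HSCs, so its genes and those of glycolysis were compared over all clusters. The autophagy list, 35 genes, stood apart on the high side in cluster 9, with a median of 0.19, 24 members above 0 and none past both limits of the size rule. The selective autophagy receptor gene Optn (0.56), the initiating kinase gene Ulk1 (0.53), Tecpr1 (0.51) and Atg2a (0.50) had the largest values there in the authors' deposited table, all 4 short of the limit on the adjusted p. In cluster 10 its median of 0.08 lay at the 0.48th percentile of matched lists, which were higher. The mean over its members lay within the limits in both clusters, at the 89.4th and 11th percentile, and the call in cluster 10 ended without 1 member. The LC3 gene Map1lc3b (-0.85), the cargo receptor gene Sqstm1 (-0.58) and Gabarap (-0.68) were lower in cluster 7 in the authors' deposited table, a cluster in which ribosomal protein genes had a median of -0.91. The autophagy list did not stand apart in clusters 0 and 2 (medians -0.03 and 0.04). There the 4 autophagy genes read in every cluster had opposite signs without passing the rule: Map1lc3b was at -0.14 and 0.06, Sqstm1 at -0.26 and 0.19, Gabarapl1 at -0.33 and 0.26, and Gabarap at -0.16 and 0.19 in the authors' deposited tables. The 2 clusters were opposed over all genes at or above the median expression (r of -0.81), so these signs are not particular to autophagy. Of the glycolysis genes, Pgk1 was at 0.24 in cluster 0 and -0.20 in cluster 2, Ldha at 0.14 and -0.18, and the glucose transporter gene Slc2a1 at -0.26 and 0.19 in the authors' deposited tables. Aldoa was lower in clusters 7 (-0.62) and 8 (-0.68) in the authors' deposited tables. Lysosome genes lay between the 4.07th and 98.2nd percentile of matched lists and heat shock genes between the 0.71st and 98.3rd, so neither list stood apart in any cluster. The B cell, neutrophil, dendritic cell and eosinophil marker lists did not either, with percentiles of 3.28 to 94.8, 16.1 to 98.0, 12.9 to 90.4 and 1.39 to 92.7.

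Relations between clusters were compared across genes, which are not independent replicates, over 55 pairs. Among genes at or above the median expression, clusters 0 and 4 had an r of -0.42 (-0.28 for independent clusters of their sizes), clusters 1 and 7 an r of -0.44 (-0.02) and clusters 4 and 6 an r of -0.48 (-0.01). Clusters 4 and 7 had an r of 0.38 (-0.01), clusters 0 and 8 an r of 0.365 (-0.06) and clusters 1 and 6 an r of 0.30 (-0.02). None of these positive values reached the limit of 0.4, and Spearman's rho over all genes was 0.12, 0.18 and 0.11 for these pairs. Clusters 6 and 7, with mitochondrial transcripts on opposite sides, had an r of -0.40 (0.13 for independent clusters of their sizes). On all genes their r was 0.52 and Spearman's rho -0.02, with undetected genes entering at very large negative folds.

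**Figure D5:**
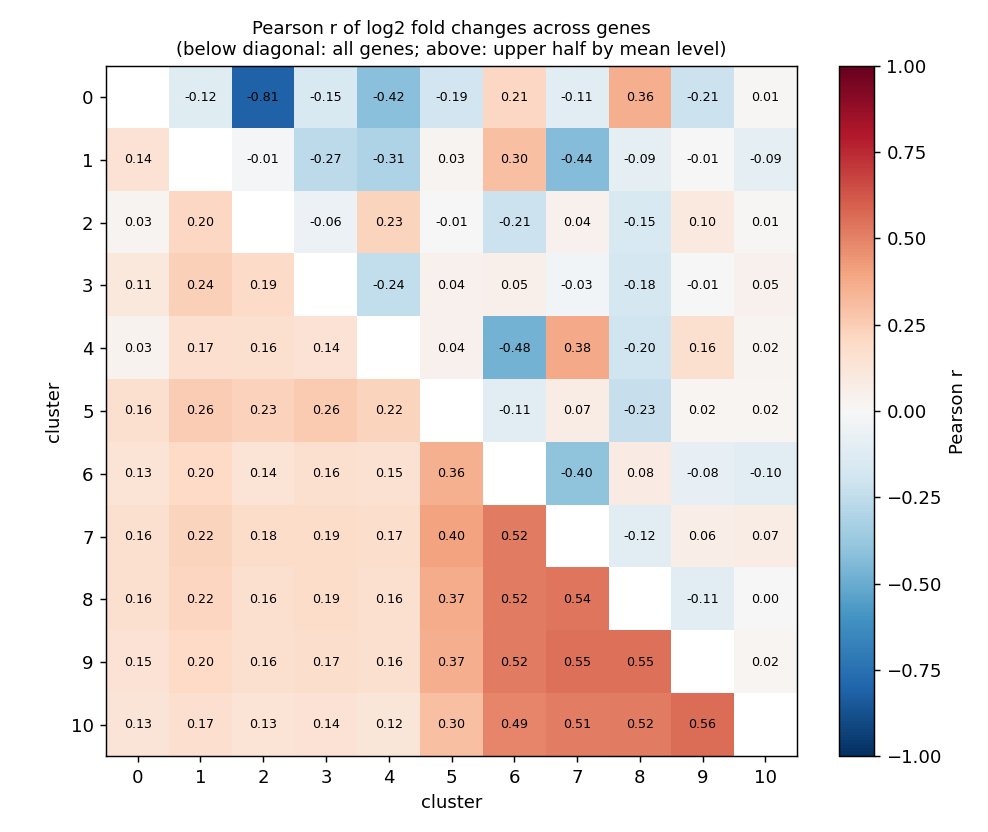
Pearson r (colour) between the log2 fold changes of each pair of clusters, with clusters on both axes, for all genes below the diagonal and for genes at or above the median expression above it. Clusters 0 and 2 are the most opposed pair above the diagonal (-0.81).

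The effects of age, of fasting and of refeeding need values for each library, and these were not analysed here. How the 6 libraries contribute to each cluster was likewise not analysed here, so no cluster is assigned to an age or a feeding condition.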

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

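Leaving out genes undetected on one side, setting undetected genes at 3 counts, and leaving out pathways scored 0 on one side were chosen after seeing the data; the other alternatives were fixed before the data were examined. No library was left out and no paired analysis was possible because the values used here are pooled over the libraries. Rarely detected genes are a limit: in clusters 5 to 10 depth and cell number leave many genes at 0, and counts of lower genes there include many undetected ones. The authors' test statistic for genes and a limit on pathway set sizes were not run, since neither was used here. Of 125 list calls, 89 held when the member that moves each most was left out, and 118 held with undetected genes at 3 counts. Named genes past the rule and detected in the cluster kept their call in 251 of 292 cases at an adjusted p under 0.001, while 163 of 292 fell short of a fold of 1. Many of these were named from the ends of the authors' order, so the share kept does not hold for all called genes. Over all genes, an adjusted p under 0.001 moved 18 counts of higher or lower genes by more than a factor of 1.5 and left 4 within it. Without ribosomal protein and mitochondrially encoded genes all 55 relations stayed within 0.1 on all genes, where undetected genes enter with very large negative folds. This alternative was not run on genes at or above the median expression, so it does not cover the relations read there. Where a value below changed, the cause was not tested unless given.

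A lower fold limit of 0.25 admits more genes by construction. Higher genes then numbered 1118, 102, 1171, 372, 578, 92, 18 and 1030 in clusters 0, 1, 2, 3, 4, 5, 6 and 8, and lower genes 1878, 941, 1087, 579 and 352 in clusters 0 to 4. A limit of 1 admits fewer: higher genes numbered 130, 2, 178, 22, 4, 8, 2, 38, 82, 99 and 98 in clusters 0 to 10, and lower genes 522, 273, 363, 197 and 2841 in clusters 0, 1, 2, 3 and 6. An adjusted p under 0.001 gave 267, 10, 340, 60, 29, 15, 0, 82, 173, 101 and 11 higher genes in clusters 0 to 10, and 690, 110, 289, 102, 45, 365 and 2837 lower genes in clusters 0 to 6. With no limit on p, higher genes numbered 1180, 624, 1461, 927, 943, 1154, 1309, 2415, 2467, 2477 and 4869 in clusters 0 to 10, and lower genes 2030, 1583, 1451, 1337, 1147 and 2134 in clusters 0 to 5.

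Without genes below the median expression, higher genes numbered 89, 7, 102, 20, 19 and 12 in clusters 0 to 5, and lower genes 167, 3, 81, 25, 1, 9, 1537, 1302, 324, 161 and 36 in clusters 0 to 10. Without ribosomal, mitochondrially encoded and provisional names, lower genes numbered 268, 499, 2190, 2083 and 2939 in clusters 1, 5, 8, 9 and 10. Without genes undetected on one side they numbered 267, 141, 151, 2083, 1615, 590, 286 and 27 in clusters 1 and 4 to 10.

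List calls on the low side, 69 in all, numbered 42 with the mean over members and 44 without each member in turn. Taking the mean moved immediate early genes of cluster 10 to the 49.16th percentile and ribosomal protein genes of cluster 1 to the 28.03rd, both across the middle. Without genes below the median expression, lymphoid priming genes moved to the 1.02nd percentile in cluster 0 and the 76.46th in cluster 2. Lymphoid-primed markers moved to the 0.26th, 66.47th, 74.05th and 98.63rd percentile in clusters 0, 2, 4 and 5, and erythroid priming genes of cluster 9 to the 99.7th.

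Most relations moved with Spearman's rho (48, and 1 reversed) and without genes below the median expression (43, and 5 reversed). Undetected genes enter Pearson r on all genes with very large negative folds, but leaving out these alone was not tested. Spearman's rho was -0.561 for clusters 0 and 2, -0.304 for 0 and 4, -0.147 for 1 and 7, -0.177 for 4 and 6, and 0.0736 for 5 and 7. For cluster 6 with clusters 7, 8, 9 and 10 it was -0.0219, 0.139, 0.0824 and 0.0969. For cluster 7 with clusters 8, 9 and 10 it was 0.0781, 0.166 and 0.186, for cluster 8 with 9 and 10 it was 0.0895 and 0.162, and for 9 and 10 it was 0.187. Without genes below the median expression, Pearson r was -0.812 for clusters 0 and 2, -0.421 for 0 and 4, -0.435 for 1 and 7, -0.476 for 4 and 6, and 0.0736 for 5 and 7. For cluster 6 with clusters 7, 8, 9 and 10 it was -0.405, 0.0846, -0.079 and -0.104. For cluster 7 with clusters 8, 9 and 10 it was -0.115, 0.0628 and 0.0713, for cluster 8 with 9 and 10 it was -0.113 and 0.001, and for 9 and 10 it was 0.0171.

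Pathway counts moved with the limit on the adjusted p by construction. Under 0.01, higher pathways numbered 96, 2, 108 and 1135 in clusters 5, 6, 7 and 10, and lower pathways 129 in cluster 5. Under 0.25, higher pathways numbered 373, 23 and 377 in clusters 5, 6 and 7, and lower pathways 675, 286 and 180 in clusters 5, 8 and 9. Without pathways scored 0 on one side, 1 lower pathway was left in cluster 10.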

Other observations

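The lists of histone genes and of the Dlk1-Meg3 locus, the damage, mitochondrial content, globin and mature cell tests, and the sampled form of the depth test for cluster 10 were chosen after the result was seen.

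Histone genes had a high median in cluster 8, on a list made after some of them were seen to lead it. The comparison with random lists therefore describes the pattern and does not test it. Of 71 measured histone genes 21 were higher there, 8 were lower and 42 did not pass, with a median log2 fold change of 1.21 in the authors' deposited table, above all 10000 matched random lists. Linker histones and core histones of the large cluster on chromosome 13, such as Hist1h2bc (4.06) and Hist1h1c (2.71), led the authors' deposited table. The S phase list did not stand apart in cluster 8. In cluster 7 the histone genes had a median of -0.82 with 38 lower, and in clusters 3 and 5 medians of -0.20 and -0.28 with 5 lower in each, from the authors' deposited tables.

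The imprinted locus on chromosome 12 that holds Dlk1 (109452823 to 109463336, mm10), Meg3 (109541001 to 109571726), Rian (109603940 to 109661716) and Mirg had all 4 genes past the size rule in one direction in 3 clusters. All 4 genes were higher in cluster 2 (median 0.98) and 3 of 4 in cluster 5 (median 1.21), and all 4 were lower in cluster 0 (median -1.19) and in cluster 3 (median -0.89) in the authors' deposited tables. Meg3 and Mirg are also members of the nuclear RNA list, so its low medians in clusters 0 and 8 are not separate from this locus. In cluster 8 the locus median was -1.85 with 3 of its genes lower in the authors' deposited table. The genes lay on 1 side of 0 in clusters 1, 6 and 9 as well, and on both sides in clusters 4, 7 and 10: Mirg was at -1.38 and Rian at 0.33 in cluster 7, and Dlk1 at -1.34 and Rian at 0.51 in cluster 10, in the authors' deposited tables.

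The median fold change of all genes lay below 0 in clusters 6 and 7 and above 0 in cluster 10, which differences in counts per cell might produce through the log scale. Read at the equivalent depth of cluster 7, one shared profile gave a median of -0.11 against the deposited -0.17, a gap of -0.0604 within the 0.1 set beforehand. Fewer counts per cell could account for part of it, but the test cannot decide. Equivalent depth was itself read from the undetected genes of the cluster, which enter the deposited median. Ribosomal protein and mitochondrially encoded genes of cluster 7 also depart from a shared profile. In cluster 6 the same reading gave -0.11 against -0.32, a gap of -0.21 and so beyond the limit. Because that computation assumes a shared profile, it excludes nothing, and depth stays open for part of the shift. In cluster 10 a first form of the test gave 0.29 against 0.12 and was replaced by sampled cells, since 10 cells miss many genes. These gave 0.06, a gap of 0.0633, which more counts per cell may explain, but equivalent depth limits this test in the same way. Doublets, another source of more counts, were not tested.

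In cluster 7 mitochondrially encoded genes were higher and ribosomal protein genes lower, as loss of cytoplasmic RNA from damaged cells might give. Beyond the pattern itself, that explanation needs nuclear RNA to be high; the list lay at the 99.77th percentile, although this call ended without 1 member. More mitochondria per cell predicted higher nuclear-encoded oxidative phosphorylation genes, and these were lower, with a median of -0.64. Ribosomal protein genes were lower as well (median -0.91), so the test cannot separate mitochondrial content from a shared fall, and this explanation stays open. Fewer counts per cell would leave the abundant mitochondrially encoded genes near 0, at -0.0132 against 1.17 measured. Nor would fewer counts move the abundant ribosomal protein genes the other way. Damage remains a hypothesis, and age and feeding stay open as explanations because they were not analysed here.

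The erythroid, T or NK and monocyte marker lists stood apart on the high side in cluster 6, although 1 of 11, 0 of 7 and 0 of 12 members passed as higher and the monocyte call ended without 1 member. A few mature blood cells inside the cluster could give this and HSC sorting should remove them, but the 3 of 9 mature cell lists beyond the limit are the pattern itself, so mature cells stay untested. Of their abundant genes, Hbb-bs had a log2 fold change of 1.99 and passed, while Hba-a1 at 3.26 and Lyz2 at 0.04 did not, in the authors' deposited table. Free RNA from one source would raise globin and other erythroid markers alike; the 7 other markers had a median 3.43 above that of 4 globin genes (5.79 and 2.36). None of the 7 passed as higher, so free RNA stays open, and no biological explanation was tested.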
